A study of Mus musculus with 16 samples.

How the data were processed

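Gene expression was measured in 16 samples of mouse CD4 T cells (strain C57/BL6 per the labels) on Illumina bead arrays. Per the labels, RNA was extracted with Trizol, cleaned up and treated with DNase, and biotin-labelled cRNA was prepared from it. The scanner software and its background setting are not given in the sources used here. The deposited table of non-normalized values holds probe intensity on a linear scale, with neither detection p-values nor control probes. The deposited series matrix holds intensity normalized between arrays by the authors, also on a linear scale, by a method not given in the sources used here. On the log2 scale each array of the first table had its highest correlation, across probes, with its own column of the second. The series matrix values were used as an alternative.

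Of 25697 probes, 23978 had 1 gene symbol in the platform annotation and 1719 had none. Some genes that the rule for named genes or a gene list had included are not reported here. Intensities were background-corrected with normexp (offset 50), quantile normalized and put on a log2 scale in limma 3.58.1 under R 4.3.3. This was the procedure fixed for files without detection p-values. A probe was taken as above background on an array when it passed the 99th percentile of that array's background. The background was a normal distribution centred on the mode of log2 intensity, its SD taken from the values below the mode. Probes above background on at least 2 of the 16 arrays were kept, which left 14501 probes, of which 13612 have a symbol, for 9800 genes. Between 12172 and 12636 probes per array were above background.

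Differences were tested with limma (lmFit and eBayes) in fits of all 16 arrays, with Benjamini-Hochberg adjustment over all kept probes and an adjusted p threshold of 0.05. Culture condition and genotype were additive terms for the comparisons between conditions and for the genotype difference over all conditions. The genotype difference was also fitted separately for the 5 pairs at day 1 and the 3 pairs before day 1, with a test of their difference. A further fit divided the day 1 pairs into 3 with TGF (transforming growth factor beta) and 2 without, taking iTreg culture as containing TGF. Each genotype and culture combination was measured on 1 array, so within a single pair only the difference is given, with no test. The labels do not say which cultures came from which animals, and the p-values measure only the spread between these samples. A fold change against a group that was never above background is given as a lower bound.

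There were 21 gene lists, fixed before the data were examined, and they include markers of B cells, myeloid cells, CD8 and NK cells and red cells. They were tested with camera in limma at a preset correlation of 0.01, with the brightest kept probe of each gene, and again with a correlation estimated from the residuals. List p-values were adjusted over the 21 lists within a comparison. Named genes follow a rule also fixed before the data were examined. It takes the 8 largest rises and 8 largest falls among called probes with a symbol and 1 direction in every pair, and up to 4 members of each list. It adds Foxp3, Tbx21, Ifng and Gata3 everywhere, and in a single pair the 3 largest changes each way. For genes named as largest changes, 1 direction in every pair follows from the rule and is no added evidence. The tests by stage and by TGF did not require it. The same rule was applied to the fit of the 3 hr pairs alone, which was chosen after the data were seen.

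The procedure was tested on simulated data with 200 of 14501 probes changed. Its noise was normal and independent between probes, with no outlying pair or array, so the rates need not hold for the real data. In the genotype contrast over all conditions it recovered 100% of changes of 0.5 on the log2 scale, with 4.31% false calls. For the difference between stages it recovered 77.6%, with 7.54% false calls, and for the difference by TGF 44.8%, with 6.32%. Over all comparisons false calls were 2% (genotype before day 1) to 7.61% (1 hr of TGF against Th0), and in most comparisons above the 5% aimed at.

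Alternatives were other background corrections and normalizations, the series matrix values, no filter, a filter at 8 arrays, a trended robust prior, array weights, other blocks, each chip alone, and leaving out each pair or array in turn. Fits with the genotype labels of the day 0 arrays exchanged, and fits without the day 0 pair or the day 1 iTreg pair where the comparison itself does not use them, were chosen after the data were seen. The neqc background correction could not be run, since it needs detection p-values or control probes. No file of the series was left unused.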

Results

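Expression was profiled in mouse CD4 T cells that were wild type (WT) or deficient in Erk2, a mitogen-activated protein kinase that acts downstream of the T cell receptor. The stated purpose of the series is to analyse how Erk2 regulates differentiation into Th1 cells and into induced regulatory T (iTreg) cells. Cells of each genotype were measured at day 0, after 3 hr in Th0 or iTreg culture, and at day 1 in Th0, Th1 or iTreg culture. Th0 is neutral culture. Further day 1 Th0 cells had received TGF (transforming growth factor beta) for 1 hr or 3 hr. These 8 conditions and 2 genotypes gave 16 arrays, 1 for each combination, so no combination was replicated and the number of arrays limits the precision.

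Median intensity per array was 62.6 to 71.1, and 12172 to 12636 of 25697 probes were above background. Time in culture was the main difference between arrays. The first principal component held 71.7% of the variance and placed day 0 at −57.8 and −57.9, the 3 hr arrays between −49.0 and −47.5, and most day 1 arrays between 30.0 and 35.1. The Erk2-deficient day 1 iTreg array was the exception, at 17.2. Day 0, the 3 hr cultures and day 1 Th0 were on 1 chip, and the other day 1 cultures on another. On both chips WT samples held the odd and Erk2-deficient samples the even positions, so position and genotype cannot be told apart.

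**Figure D1:**
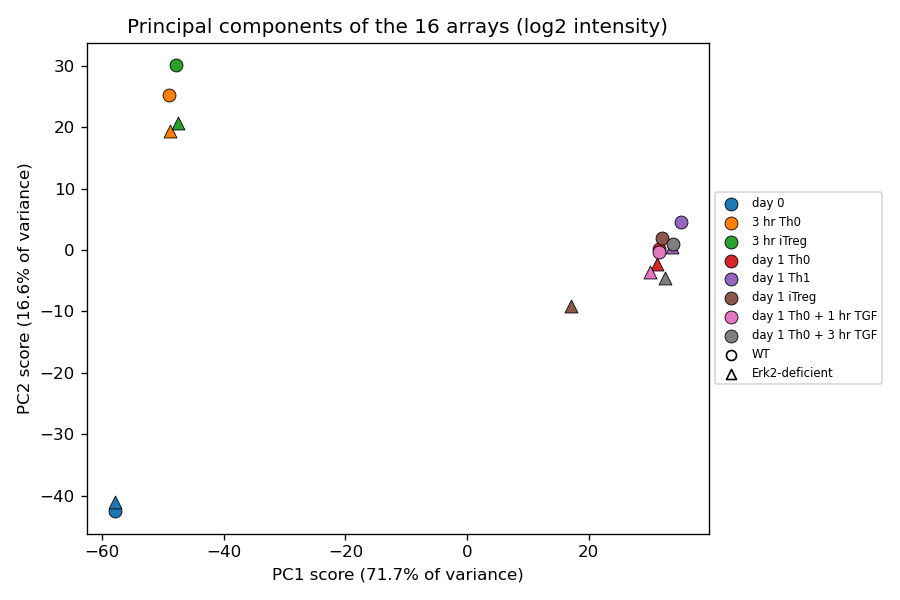
The 16 arrays on the first 2 principal components of log2 intensity, by culture condition and genotype. Day 0 and 3 hr arrays have negative scores on the first component (71.7% of the variance) and day 1 arrays positive ones, with the Erk2-deficient day 1 iTreg array lowest among these at 17.2.

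The first comparison asked how Erk2-deficient cells differed from WT cells after 1 day of culture, over 5 pairs. In Erk2-deficient cells 6 of 20 ERK-responsive and feedback genes were lower, and 4 of 15 naive and quiescence genes, Gata3 and Foxp3 were higher. The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.171 and adjusted p = 0.191). Egr1, an immediate early transcription factor, was 4.09-fold lower (log2 difference −2.03, SE 0.211, adjusted p = 7.19e-05, lower in 5 of 5 pairs). Its difference was only −0.66 in the iTreg pair, against −2.09 to −2.65 in the other day 1 pairs. Gata3, the lineage factor of Th2 cells, was 1.94-fold higher (log2 difference 0.95, SE 0.0548, adjusted p = 1.25e-07, higher in 5 of 5 pairs). Foxp3, the lineage factor of regulatory T cells, was 1.52-fold higher (log2 difference 0.61, SE 0.103, adjusted p = 0.00349, higher in 5 of 5 pairs), and its other 2 probes differed by 0.58 and 0.35. In all, 576 of 14501 probes differed, 333 higher and 243 lower in Erk2-deficient cells, 16 of them at least 2-fold, and 557 had the same direction in all 5 pairs.

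On the GRCm38 assembly, Egr1 (gene ID 13653) lies on chromosome 18 from 34861207 to 34864956. Gata3 (14462) lies on chromosome 2 from 9857078 to 9887953, and Foxp3 (20371) on chromosome X from 7579676 to 7595243.

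Of 20 measured ERK-responsive and feedback genes, 6 were lower at day 1 and none was higher, with 7 lower when adjusted over the list alone (camera adjusted p = 2.36e-05; adjusted p = 0.171 with an estimated correlation). Beside Egr1 these were Egr2 (log2 difference −1.15), Dusp6, a phosphatase that inactivates ERK (−1.27 and −1.17 on 2 probes), Dusp4 (−0.77), Fosl1 and Junb. The other large falls were in Pdgfb, a growth factor (−1.49), Rgs16, a regulator of G protein signalling (−1.39), the chemokine Ccl1 (−1.09), Cpped1 (−1.05) and Nrn1 (−0.90). Of 18 T cell activation genes 5 were lower, Cd69, Cd44, Tnf, Xcl1 and Rel, with 8 lower when adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.615 with an estimated correlation). Of 10 ERK cascade components, Rasgrp1 alone passed, and it was higher by 0.53 (1 when adjusted over the list alone; camera adjusted p = 0.489).

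Of 15 naive and quiescence genes, 4 were higher and none lower, with 8 higher when adjusted over the list alone (camera adjusted p = 2.57e-07; adjusted p = 0.191 with an estimated correlation). The list's median was 0.509 in the iTreg pair, whose Erk2-deficient array stood apart on the first principal component, and 0.0912 to 0.218 in the other 4 pairs. The genes that passed were Klf2, a transcription factor of resting T cells (log2 difference 0.96), Tsc22d3 (0.92 on one probe and 0.17 on another), Igfbp4 (0.48) and Lef1. Eno3 (1.43), Pdlim4 (1.25), Ptprk (1.17), Nsg2 (0.96) and Gpr183 (0.87) were among the largest rises. Of 7 Th2 genes 3 were higher, Gata3, Il4 (0.69) and the chemokine receptor Ccr8 (0.80), with 3 when adjusted over the list alone (camera adjusted p = 7.39e-05; adjusted p = 0.131 with an estimated correlation). Of 16 Treg genes 5 were higher, Foxp3, Ctla4 (0.49), Tnfrsf18, Ikzf4 and Swap70 (0.50), and Capg was lower (−0.53). When adjusted over the list alone 8 were higher and 2 lower (camera adjusted p = 0.000191; adjusted p = 0.171 with an estimated correlation).

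Of 16 Th1 genes, Il18r1 alone passed, and it was higher by 0.50 (1 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.194). Ifng, the main Th1 cytokine, differed by −0.02 (adjusted p = 0.942), and Tbx21, the lineage factor of Th1 cells, by −0.42 (adjusted p = 0.12; 0.031 without the day 0 pair). Of 18 interferon response genes 3 were higher, Ifit2, Ifit3 (0.76) and Usp18 (0.66), with 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0404; adjusted p = 0.474 with an estimated correlation). The ribosome biogenesis list shifted down with no member past the threshold and 2 when adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.537 with an estimated correlation). Glycolysis shifted down with none by either count (camera adjusted p = 0.0405; adjusted p = 0.551 with an estimated correlation). The other 11 lists had a camera adjusted p of 0.101 or more, among them cell cycle (0.488) and TGF-beta and Smad response (0.488). Of 5 Th17 genes Ccr6 was higher (1 when adjusted over the list alone; camera adjusted p = 0.865, upward, with a list median of −0.04). Of the markers of other cells, S100a8 was higher among 10 myeloid genes (2 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.865) and Nkg7 among 7 CD8 and NK cell genes (2 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.101). None of 10 B cell genes passed (0 when adjusted over the list alone, camera adjusted p = 0.428), nor any of 3 red cell genes (1 lower when adjusted over the list alone, camera adjusted p = 0.306). Hba-a1 was nevertheless lower in all 5 day 1 pairs (−0.51 to −2.33). The variance in this fit also takes in its day 0 and 3 hr pairs, which ran opposite to each other.

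Without 1 pair the day 1 count was 348 (Th0), 276 (Th1), 364 (iTreg), 328 (1 hr TGF), 232 (3 hr TGF) or 921 (day 0, which shares the fit and kept all 576 probes), and with array weights it was 974. The second Dusp6 probe was lost without the Th1 (adjusted p = 0.0531), 1 hr TGF (0.0508) or 3 hr TGF pair (0.081), Il18r1 and Ifit3 without the 3 hr TGF pair (0.104 and 0.0683), S100a8 and Capg in 4 and Tnf in 5 of the fits without a day 1 pair, and Xcl1, Ifit2 and the dimmest Foxp3 probe in 3 or 4.

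**Figure D2:**
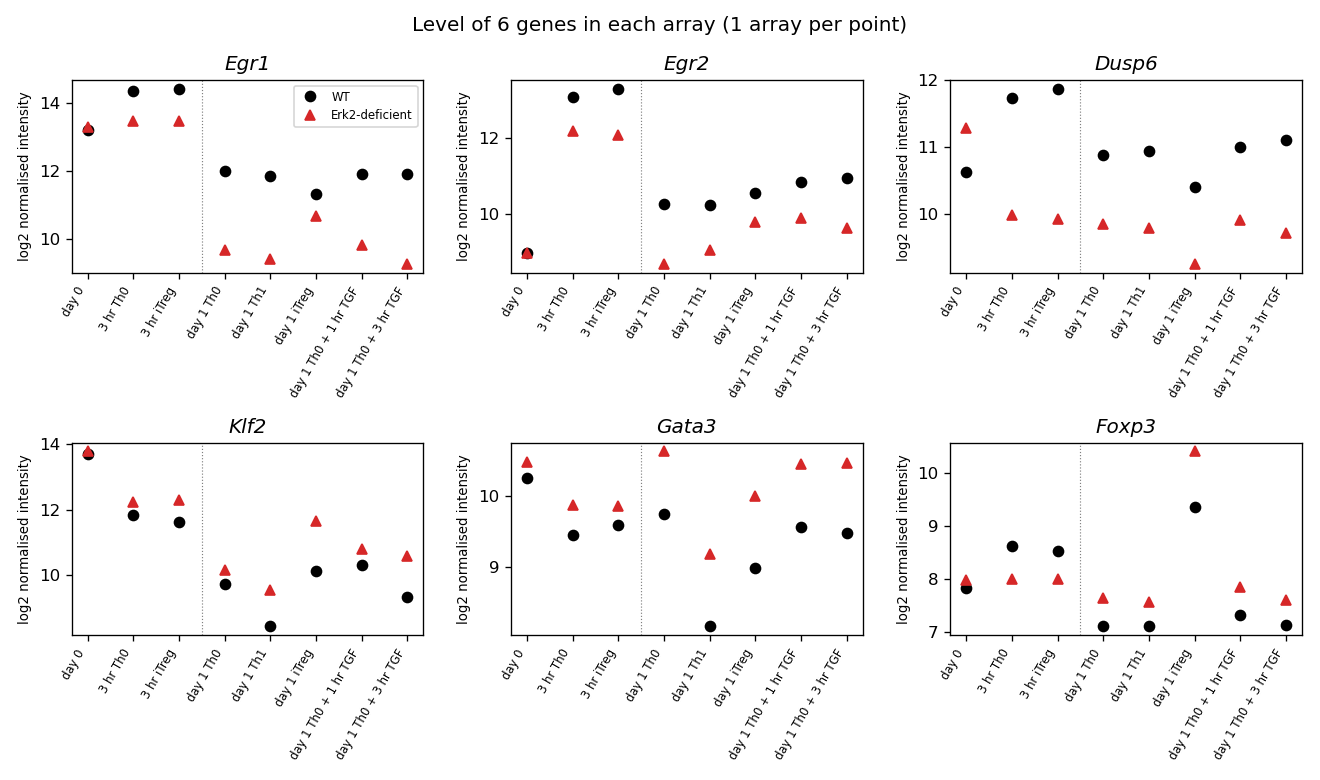
Log2 intensity of Egr1, Egr2, Dusp6, Klf2, Gata3 and Foxp3 on each array, WT as black circles and Erk2-deficient as red triangles, 1 array per symbol. At day 1 Egr1, Egr2 and Dusp6 were lower in Erk2-deficient cells and Klf2, Gata3 and Foxp3 higher in all 5 pairs.

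Over all 8 conditions, 500 probes differed between genotypes, 261 higher and 239 lower in Erk2-deficient cells, 10 of them at least 2-fold, and 274 had the same direction in all 8 pairs. Egr2 was lower in all 7 cultured pairs, with −0.003 at day 0 (log2 difference −0.98, SE 0.119, adjusted p = 0.000895), as were Ccl1 (−0.97) and the kinase Jak2 (−0.59), each with −0.017 at day 0. Slamf1, a costimulatory receptor (−0.71), the cytokine Lta (−0.68), Axl (−0.67, with −0.055 at day 0), Gfod1 (−0.61) and Sema7a (−0.60) were lower in 8 of 8 pairs. Gata3 was higher in 8 of 8 pairs (log2 difference 0.71, SE 0.0901, adjusted p = 0.00106), as were Gpr183 (0.69), Ccr8 (0.62), Vim (0.59) and Mapre2 (0.51). Klf2 (0.75), Adh1 (0.58) and Thy1 (0.51) were higher with little difference at day 0 (0.075, 0.059 and 0.067). Egr1 (−1.48) and Dusp6 (−1.11) were lower in 7 of 8 pairs. Foxp3 (0.26, adjusted p = 0.344) and Ifng (−0.29, adjusted p = 0.22) did not pass, and Tbx21 was lower by a small margin (−0.43, adjusted p = 0.0478, lower in 7 of 8 pairs).

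The same 6 ERK-responsive genes were lower as at day 1 (9 when adjusted over the list alone; camera adjusted p = 1.66e-05; adjusted p = 0.384 with an estimated correlation). Of 18 T cell activation genes 7 were lower (8 when adjusted over the list alone; camera adjusted p = 0.00043; adjusted p = 0.427 with an estimated correlation), among them Tnf (−0.84), Xcl1 (−0.55) and Lta. Of 15 naive and quiescence genes 4 were higher (8 when adjusted over the list alone; camera adjusted p = 1.66e-05; adjusted p = 0.427 with an estimated correlation). Of 16 Th1 genes Tbx21, Il12rb1 (−0.47) and Fasl (−0.45) were lower (7 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.00139; adjusted p = 0.427 with an estimated correlation). Lyz1 (−0.67) and Ifitm3 (−0.26) of the myeloid markers were lower too (2 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.444, downward, with a list median of 0.003).

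Chip 1 alone, which holds the day 0 pair, gave 0 calls by limma (1411 probes at an unadjusted p under 0.05) and chip 2 alone 420, and chip as the only block gave 0 (363 unadjusted). Leaving out 1 pair gave 968 (day 0), 282 (3 hr Th0), 287 (3 hr iTreg), 275 (day 1 Th0), 222 (day 1 Th1), 213 (1 hr TGF) or 148 probes (3 hr TGF), and the calls of Tbx21, Il12rb1, Fasl, Lyz1 and Ifitm3 were each lost in 5 to 7 of the 8 fits.

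Over the 3 pairs before day 1, limma called 0 probes for genotype, with 1644 at an unadjusted p under 0.05. For some genes the day 0 pair ran opposite to the 3 hr pairs, and for others the same way. Ccr7, a homing receptor of naive T cells, did not pass but was higher in all 3 pairs (0.61 at day 0, 0.05 and 0.61 at 3 hr). Dusp6 was higher in the array labelled Erk2-deficient at day 0 (log2 difference 0.66) and lower in the 3 hr pairs (−1.75 and −1.96). The 2 largest differences in the day 0 pair were in Gdpd3 (−3.49) and Hba-a1, a haemoglobin gene (3.21), and each ran the other way in both 3 hr pairs, at 2.74 and 2.68 for Gdpd3 and at −3.46 and −3.43 for Hba-a1. In the pairs, 6 probes differed at least 2-fold at day 0, against 28 in 3 hr Th0 and 56 in 3 hr iTreg culture. Of the lists, T cell activation (6 of 18 lower when adjusted over the list alone, none over all probes) and Th1 (6 of 16, none over all probes) had camera adjusted p = 7.79e-06 and 5.37e-06. With an estimated correlation these were adjusted p = 0.489 and adjusted p = 0.286. Without the day 1 iTreg pair in the fit 90 probes passed, with array weights 277, and with the genotype labels of the day 0 arrays exchanged 192.

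In a fit of the 3 hr pairs without day 0, chosen after the data were seen, 500 probes differed, 178 higher and 322 lower in Erk2-deficient cells. Cxcl9, an interferon-induced chemokine, was 3.86-fold lower (log2 difference −1.95, SE 0.154, adjusted p = 1.32e-06), Dusp6 3.62-fold (−1.85, SE 0.0976, adjusted p = 1.3e-08), the cytokine Tnf 2.93-fold (−1.55, SE 0.139, adjusted p = 5.16e-06) and the nuclear receptor Nr4a2 2.73-fold (−1.45, SE 0.0868, adjusted p = 4.74e-08), each in 2 of 2 pairs. Lta (−1.44) and Rgs16 (−1.36) were lower as well. Beside Gdpd3, the largest rises were in Pdlim4 (0.93), Gtf2ird1 (0.86), Eno3 (0.81), Mapre2 (0.81), Phlda3 (0.77), Klf7 (0.73) and Lad1 (0.72).

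At 3 hr, 5 of 18 T cell activation genes were lower, Tnf, Lta, Xcl1 (−0.93), Il2ra, a chain of the IL-2 receptor (−0.89), and Nr4a3, and 12 when adjusted over the list alone (camera adjusted p = 3e-12; adjusted p = 0.0427 with an estimated correlation). Of 16 Th1 genes 6 were lower, Ifng (−0.98 and −0.77 on 2 probes), Tbx21 (−0.78), Ccl3 (−1.21), Fasl (−0.97), Ccl4 (−0.83) and Cxcr3, and 8 when adjusted over the list alone (camera adjusted p = 3.74e-08; adjusted p = 0.0303 with an estimated correlation). Of 20 ERK-responsive genes Dusp6, Egr2 (−1.04), Spred1 (−0.57) and Dusp4 were lower, and 11 when adjusted over the list alone (camera adjusted p = 5e-06, and adjusted p = 0.0462 with an estimated correlation). Egr1 did not pass over all probes at 3 hr (−0.90, adjusted p = 0.114). Of 16 Treg genes Foxp3, Il2ra and Capg were lower and Swap70 higher, with 8 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.000302; adjusted p = 0.0427 with an estimated correlation). Foxp3 was lower on 2 of its 3 probes (log2 differences −0.57, adjusted p = 0.0147, and −0.58, adjusted p = 0.0084), and Gata3 was higher (0.35, adjusted p = 0.0368).

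Of 17 TGF-beta and Smad response genes, Cdkn1a (−1.20), Tgfbr1 (−0.43), Tgif1 (−0.41) and Tgfbi (−0.38) were lower at 3 hr, and 5 when adjusted over the list alone (camera adjusted p = 1.74e-05; adjusted p = 0.0427 with an estimated correlation). Some markers of other cells were lower in the same arrays. The share of other cells was not tested. The falls at 3 hr, such as those of Cxcl9 and Tnf, therefore cannot be credited to T cells alone. Of 10 myeloid markers Lyz1 (−1.43), Lyz2 (−0.96) and S100a9 (−0.78) were lower, and 7 when adjusted over the list alone (camera adjusted p = 1.61e-06; adjusted p = 0.0427 with an estimated correlation). Of 10 B cell markers H2-Ab1 (−0.69), Cd74 (−0.57) and H2-Aa (−0.45), which antigen-presenting cells share, were lower, and 3 when adjusted over the list alone (camera adjusted p = 0.0557, downward, with a list median of 0.018). Of 3 red cell markers Hba-a1 and Alas2 were lower, with 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00276; adjusted p = 0.148 with an estimated correlation). None of 7 CD8 and NK cell markers passed (0 when adjusted over the list alone; camera adjusted p = 0.761). Of the 500 probes called at 3 hr, 174 were also among the 921 called at day 1 in this fit, and 159 of the 174 had the same direction. Independent calls would give an overlap of 31.8. Both sets share 1 variance per probe in the same fit, so that number is not a fair reference and the overlap was not tested. These p-values rest on 2 pairs at 3 hr and on the spread within all 7 pairs.

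**Figure D3:**
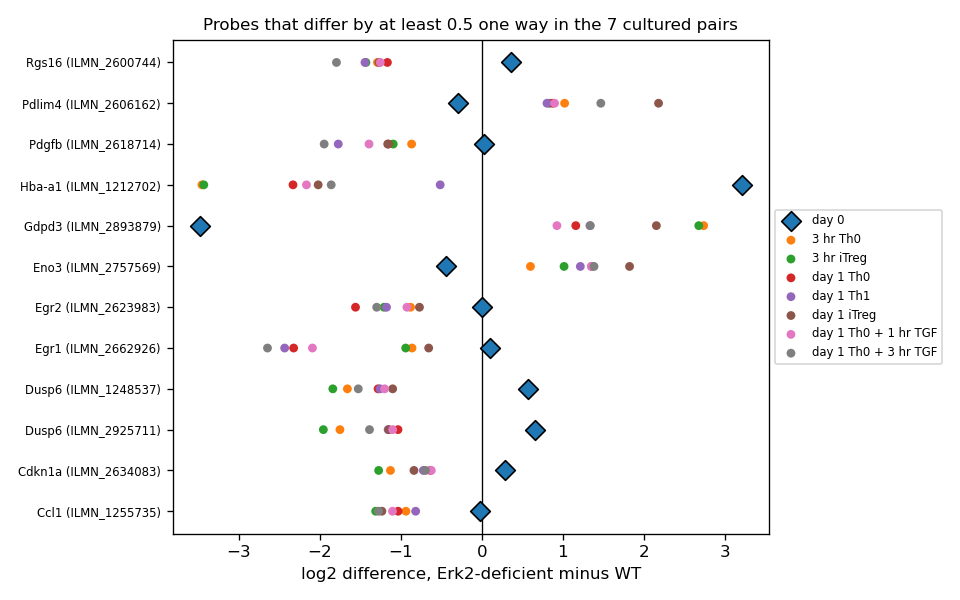
Log2 difference, Erk2-deficient minus WT, of named genes that differed by at least 0.5 in the same direction in all 7 cultured pairs, 1 symbol per pair and diamonds for day 0. In the day 0 pair Gdpd3 (−3.49), Hba-a1 (3.21) and Dusp6 (0.66) lie on the other side of 0 from the 7 cultured pairs.

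Whether the genotype difference changed between stages was tested directly. For 15 probes the difference at day 1 departed from that before day 1, 8 upward and 7 downward. Foxp3 went from −0.32 before day 1 to 0.61 at day 1 (change 0.93, SE 0.168, adjusted p = 0.0497), Gata3 from 0.31 to 0.95 (change 0.64, SE 0.0895, adjusted p = 0.00695) and the cytokine gene Il4 from −0.09 to 0.69 (change 0.78, SE 0.127, adjusted p = 0.0227). For Foxp3 the pairs before day 1 differed in sign (0.16 at day 0, −0.61 and −0.52 at 3 hr), and its other probes were not called. Ptprk, a receptor phosphatase (1.11), Nkg7 (0.86), Ahcyl2 (0.83) and Cd86 (0.59) changed upward as well, and Exoc2 (−0.78), the T cell surface proteins Cd6 (−0.66) and Cd5 (−0.65), and Ccng1 (−0.56) downward. Of 16 Treg genes, 7 changed upward when adjusted over the list alone, against Foxp3 alone over all probes (camera adjusted p = 3.63e-07; adjusted p = 0.0527 with an estimated correlation). Of 7 Th2 genes Gata3 and Il4 changed upward, and 3 when adjusted over the list alone (camera adjusted p = 3.18e-06; adjusted p = 0.0527 with an estimated correlation).

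Without the day 0 pair 179 probes changed between stages, 143 upward and 36 downward, with the 15 among them, and with its labels exchanged 71. Without the 3 hr iTreg pair 4 probes passed, without the day 1 iTreg pair 41, and without any other single day 1 pair 9. The calls of Foxp3 (adjusted p up to 0.247), Cd86 and Ccng1 were lost without any pair but day 0 or day 1 iTreg, that of Il4 without the 3 hr iTreg (0.117), day 1 Th0 (0.104) or a TGF pair (0.0831 and 0.1), and those of Gata3 (0.0548), Ptprk (0.0503) and Exoc2 (0.0503) without the 3 hr iTreg pair.

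Whether the genotype difference at day 1 depended on TGF was tested with the 3 pairs that had TGF against the 2 that did not. Limma called 0 probes, with 382 at an unadjusted p under 0.05. Foxp3 differed by 0.18 (adjusted p = 1) and Gata3 by 0.01 (adjusted p = 1). In the iTreg pair alone the genotype difference of Foxp3 was 1.05. It was 0.53 and 0.46 with 1 hr and 3 hr of TGF, 0.54 in Th0 and 0.45 in Th1 culture. The grouping by TGF does not test iTreg culture on its own. The naive and quiescence list had a larger genotype difference by camera in the 3 pairs taken as having TGF, with no single gene past the threshold by either adjustment, over all probes or over the list alone (0 of 15, camera adjusted p = 8.4e-05; adjusted p = 0.787 with an estimated correlation). Its median genotype difference was 0.509 in the iTreg pair, whose Erk2-deficient array stood apart on the first principal component, against 0.216 and 0.218 in Th0 culture with 1 hr and 3 hr of TGF, 0.165 in Th1 and 0.0912 in Th0.

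Culture in Th0 for 3 hr was compared with day 0 in both genotypes. Activation, other effects of time in culture and a change in the share of other cells cannot be told apart in this comparison. Of 18 T cell activation genes 16 rose, and of 15 naive and quiescence genes 11 fell, with both camera calls lost with an estimated correlation (adjusted p = 0.249 and adjusted p = 0.307). Sema7a rose 33.7-fold (log2 change 5.08, SE 0.243, adjusted p = 5.62e-10), Irf4 28.2-fold (4.82, SE 0.15, adjusted p = 5.82e-12), Irf8 (4.58), Ccr8 (4.58), the chemokine Ccl4 (4.54), Crem (3.65), Egr2 (3.65) and Nr4a3 (3.59), all in 2 of 2 genotypes. The largest falls were in Dtx1 (−4.12), Igfbp4 (−3.70), Pdlim4 (−3.24), Fosb (−3.15), the heat shock gene Hspa1a (−3.14), Sema4a (−2.99), Fos (−2.93) and Ppp1r15a (−2.90). In all, 6261 probes changed, 3143 upward and 3118 downward, and 986 at least 2-fold.

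Of 18 T cell activation genes 16 rose and Batf fell, with 17 and 1 when adjusted over the list alone (camera adjusted p = 6.56e-11; adjusted p = 0.249 with an estimated correlation), such as Xcl1 (3.44) and Tnf (3.31). Of 14 ribosome biogenesis genes 12 rose, and 12 when adjusted over the list alone (camera adjusted p = 4.37e-07; adjusted p = 0.249 with an estimated correlation), such as Pes1 (1.79) and Nip7 (1.51). Of 15 naive and quiescence genes 11 fell and Satb1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 1.18e-05; adjusted p = 0.307 with an estimated correlation), such as Tsc22d3 (−2.44) and Dapl1 (−2.20). Of 18 interferon response genes 13 fell and Gbp2 (2.35) and Igtp (1.83) rose, again with the same counts when adjusted over the list alone (camera adjusted p = 0.00133; adjusted p = 0.307 with an estimated correlation). Tbx21 rose by 2.58 and Ifng by 1.09 and 0.83 on 2 probes, while Gata3 fell by 0.70 (lost without the WT day 0 array, adjusted p = 0.108, or the Erk2-deficient 3 hr Th0 array, 0.0772). The second Ifng probe was lost without the WT day 0 (0.0965) or WT 3 hr Th0 array (0.061). Of 10 myeloid markers 6 fell, such as Lyz1 (−1.38), and 6 when adjusted over the list alone (camera adjusted p = 0.0528).

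Day 1 Th0 culture was compared with day 0 as well, with the same limit on what can be credited to activation. All 26 measured cell cycle genes rose against day 0, and 26 when adjusted over the list alone (camera adjusted p = 5.32e-18; adjusted p = 0.128 with an estimated correlation), such as Top2a (log2 change 3.67), Rrm2 (3.60) and Tyms (3.50). All 14 ribosome biogenesis genes rose, and 14 when adjusted over the list alone (camera adjusted p = 2.08e-06; adjusted p = 0.207 with an estimated correlation). Of 14 glycolysis genes 11 rose and Slc2a3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.000159; adjusted p = 0.207 with an estimated correlation), such as Hk2, the first enzyme of the pathway (4.35), and Tpi1 (2.92). Of 14 cholesterol biosynthesis genes 9 rose, and 9 when adjusted over the list alone (camera adjusted p = 0.00189; adjusted p = 0.223 with an estimated correlation), such as Cyp51 (1.77) and Idi1 (1.69).

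All 15 naive and quiescence genes fell by day 1, and 15 when adjusted over the list alone (camera adjusted p = 3.9e-07; adjusted p = 0.207 with an estimated correlation), such as Il7r (−3.87) and Klf2 (−3.82). Fos fell 72.5-fold (log2 change −6.18, SE 0.173, adjusted p = 4.31e-13), Hspa1a at least 73.5-fold, and Fosb (−5.65), Sgk1 (−5.60), Ppp1r15a (−5.30), Cxcr4 (−5.08) and Dusp1 (−4.63) fell likewise. Irf8 (4.53), Irf4 (4.38), Ccl4 (4.21), Pclaf (4.10), Socs2 (4.02) and Tnfrsf4 (3.96) rose, and Bcat1 rose at least 16.2-fold. Of 18 interferon response genes 15 fell and 2 rose, with the same counts when adjusted over the list alone (camera adjusted p = 2.21e-05; adjusted p = 0.207 with an estimated correlation). Of 10 myeloid markers 9 fell, and 9 when adjusted over the list alone (camera adjusted p = 0.00189; adjusted p = 0.299 with an estimated correlation), such as Lyz1 (−2.71) and S100a8 (−2.66). In all, 8700 probes changed, 4422 upward and 4278 downward, 2568 of them at least 2-fold.

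At day 1, iTreg and Th1 cultures differed in Foxp3 and Ifng. Foxp3 was 5.81-fold higher in iTreg culture (log2 difference 2.54, SE 0.282, adjusted p = 2.6e-05, higher in 2 of 2 genotypes; 1.45 and 2.40 on its other probes), and Ifng was 11-fold lower (−3.46, SE 0.233, adjusted p = 1.47e-07, lower in 2 of 2 genotypes). Emp1 was 13.3-fold higher (3.73, SE 0.231, adjusted p = 5.22e-08), followed by the protease Ctsw (3.58), the channel Aqp3 (3.54), Nt5e, which makes adenosine (3.22), Ccr8 (2.68), H2-DMa (2.66) and Capg (2.56), and Il12a was at least 5.86-fold higher. The chemokine Ccl3 (−2.26), Nrn1 (−2.24), Ifitm3 (−1.98), Chst2 (−1.86), Plac8 (−1.77), Gimap7 (−1.73) and Gbp5 (−1.71) were lower. Gata3 was higher (0.82, adjusted p = 0.00867; 0.148 without the WT Th1 and 0.116 without the Erk2-deficient iTreg array), and Tbx21 did not pass (−0.70, adjusted p = 0.0709; 0.00177 without the WT iTreg array and 0.0331 without the day 0 pair).

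Of 16 Treg genes 9 were higher in iTreg than in Th1 culture, with 11 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.29e-11; adjusted p = 0.142 with an estimated correlation), such as Ikzf4 (1.89) and Itgae (1.31). Of 17 TGF-beta and Smad response genes 8 were higher and Id3 lower, with 9 and 2 when adjusted over the list alone (camera adjusted p = 1.54e-06; adjusted p = 0.177 with an estimated correlation), such as Tgfbr1 (2.36), Id1 (1.19) and Tgfbr2 (1.08). Of 16 Th1 genes 7 were lower, with 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.7e-06; adjusted p = 0.142 with an estimated correlation). Of 14 glycolysis genes 5 were lower, and 11 when adjusted over the list alone (camera adjusted p = 1.54e-06; adjusted p = 0.142 with an estimated correlation). In all, 1237 probes differed, 690 higher and 547 lower in iTreg culture, 167 at least 2-fold. Leaving out 1 array gave 535 (WT Th1), 503 (Erk2-deficient Th1), 2291 (WT iTreg) or 602 (Erk2-deficient iTreg).

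The next 4 comparisons set a day 1 culture on the second chip against day 1 Th0 on the first, so chip and culture cannot be told apart within any 1 of them. An effect of chip alone would be alike in all 4, but the probes called were 16 (Th1), 952 (iTreg), 33 (1 hr of TGF) and 168 (3 hr of TGF). This argues against chip as the source of most calls in iTreg culture. Th1 culture differed from Th0 at 16 probes, 7 higher and 9 lower. Ifng was 6.21-fold higher (log2 difference 2.63, SE 0.249, adjusted p = 0.000124, higher in 2 of 2 genotypes) and Gata3 2.86-fold lower (−1.51, SE 0.18, adjusted p = 0.00122; 0.0582 without the WT Th1 array). Furin (1.01) and Gadd45g (0.79) were higher, and Pros1 (−1.93), H2-DMa (−1.74), Hemk1, Slc2a6, Casp6, Pdcd4 and Grap lower. Of 16 Th1 genes Ifng alone was higher, and 6 when adjusted over the list alone (camera adjusted p = 1.36e-06; adjusted p = 0.271 with an estimated correlation), while Tbx21 did not pass (−0.04). Leaving out 1 array gave 4 (WT Th0), 10 (Erk2-deficient Th0), 6 (WT Th1) or 8 probes (Erk2-deficient Th1), the fit gave 25 without the day 0 pair and 53 without the iTreg pair, and only the calls of Ifng and Pros1 among the named genes held in every fit without 1 array.

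Against day 1 Th0, iTreg culture had 952 probes past the threshold, 518 higher and 434 lower, 139 at least 2-fold. Emp1 was 19.2-fold higher (log2 difference 4.26, SE 0.231, adjusted p = 1.25e-08) and Foxp3 5.69-fold higher (2.51, SE 0.282, adjusted p = 3.3e-05), both in 2 of 2 genotypes. Ctsw (3.52), Aqp3 (3.06), Nt5e (2.99), Pdgfb (2.74), Dusp4 (2.63) and Adam19 (2.57) were higher, and Nrn1 (−2.06), Gbp5 (−1.80), the transcriptional repressor Gfi1 (−1.74), Gbp2 (−1.72), Gimap7 (−1.69), Tg (−1.57), Btla (−1.49) and Ifitm3 (−1.46) lower. Of 16 Treg genes 7 were higher, and 9 when adjusted over the list alone (camera adjusted p = 7.07e-11; adjusted p = 0.172 with an estimated correlation). Of 17 TGF-beta and Smad response genes 7 were higher and 1 lower, with 10 and 1 when adjusted over the list alone (camera adjusted p = 2.41e-08; adjusted p = 0.21 with an estimated correlation). Leaving out 1 array gave 384 (WT Th0), 383 (Erk2-deficient Th0), 1720 (WT iTreg) or 571 (Erk2-deficient iTreg).

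After 1 hr of TGF, 33 probes differed from day 1 Th0, 31 of them higher. Rgs16 was 3.74-fold higher (log2 difference 1.90, SE 0.318, adjusted p = 0.0212), Dusp4 3.29-fold (1.72, SE 0.236, adjusted p = 0.00398), Spsb1 3.03-fold (1.60, SE 0.164, adjusted p = 0.000878), and Nt5e (1.20), Phlda1 (1.14), the receptor Tgfbr1 (1.11), Endod1 (1.07) and Skil, a Smad repressor (1.00), were higher too, all in 2 of 2 genotypes. Gfi1 (−0.72) and Nrros (−0.64) were lower. Of 17 TGF-beta and Smad response genes Skil and Tgfbr1 were higher, and 5 when adjusted over the list alone (camera adjusted p = 2.45e-09; adjusted p = 0.302 with an estimated correlation). Foxp3 differed by 0.21 (adjusted p = 1). Leaving out 1 array gave 1 (WT Th0), 4 (Erk2-deficient Th0), 4 (WT 1 hr TGF) or, by limma, 0 probes (Erk2-deficient 1 hr TGF, with 493 at an unadjusted p under 0.05), and the call of each named gene was lost in at least 1 of these fits.

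After 3 hr of TGF, 168 probes differed from day 1 Th0, 125 higher and 43 lower, 30 at least 2-fold. Pdgfb was 4.71-fold higher (log2 difference 2.24, SE 0.3, adjusted p = 0.000812) and Dusp4 4.53-fold (2.18, SE 0.236, adjusted p = 0.000129). Rgs16 (1.96), Nt5e (1.81), Emp1 (1.80), Endod1 (1.80), Adam19 (1.63) and Lpxn (1.60) were higher too, and Gpr183 (−1.33), St8sia4 (−1.20), Gfi1 (−1.19), Cd226 (−0.85), Eomes, a T-box factor (−0.82), Trat1, Cd53 and Tespa1 lower. Of 17 TGF-beta and Smad response genes Skil (0.85) and Tgfbr1 (1.17) were higher, and 4 when adjusted over the list alone (camera adjusted p = 0.00178; adjusted p = 0.502 with an estimated correlation). Foxp3 differed by −0.01 (adjusted p = 1). Leaving out 1 array gave 53 (WT Th0), 50 (Erk2-deficient Th0), 54 (WT 3 hr TGF) or 81 (Erk2-deficient 3 hr TGF), and the fit gave 282 without the iTreg pair. The calls of Rgs16, Gpr183, Eomes, Trat1, Cd53, Tespa1 and Skil were each lost in 2 to 4 of the 4 fits without 1 of these arrays.

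Both TGF times were on the second chip and could be compared directly. From 1 hr to 3 hr, 22 probes rose and 6 fell, none of them 2-fold. Lpxn, an adaptor protein (log2 change 0.98, SE 0.107, adjusted p = 0.000927), and the cell division genes Ube2c (0.92) and Cenpa (0.76) rose, together with Tubb6 (0.94), Apol9b (0.89), Arhgap24 (0.81), Pik3cg (0.76) and Tmem184b (0.72). St8sia4 (−0.87), Cd226, a costimulatory receptor (−0.87), Vav3 (−0.67), Atm (−0.58) and Tmem131l (−0.55) fell. Of 26 cell cycle genes Ccna2 and Plk1 rose, and 5 when adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.838 with an estimated correlation). Leaving out 1 array gave 7 (WT 1 hr), 7 (Erk2-deficient 1 hr), 9 (WT 3 hr) or 15 probes (Erk2-deficient 3 hr), and the fit gave 71 without the iTreg pair. Of the genes given with a value, Lpxn, Apol9b, Cenpa, Tmem184b and Cd226 passed in each of these fits and the others were lost in at least 1.

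For 3 hr iTreg against 3 hr Th0 culture, limma called 0 probes in the fit of all arrays, with 528 at an unadjusted p under 0.05, and 1 without the WT 3 hr iTreg array. In the fit of all arrays no list passed by camera (lowest adjusted p = 0.264). Foxp3 differed by −0.05 and Gata3 by 0.06, and neither passed.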

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

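The tests of the day 0 pair, and those of a dim array and of weaker activation for the iTreg array, were chosen after the results were seen, while the counts of other splits and the test of mixed RNA were fixed before.

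For 15 probes the genotype difference at day 1 departed from that before day 1 by limma's interaction test. The change was 1.62 for an unnamed probe (ILMN_2656854; 0.07 before day 1, 1.69 at day 1), 1.11 for Ptprk (0.06, 1.17), 0.93 for Foxp3 (−0.32, 0.61), 0.86 for Nkg7 (−0.08, 0.78) and 0.83 for Ahcyl2 (−0.26, 0.57). It was 0.78 for Il4 (−0.09, 0.69), 0.64 for Gata3 (0.31, 0.95) and 0.595 for Cd86 (−0.16, 0.44). Downward it was −0.56 for Ccng1 (0.28, −0.28), −0.65 for Cd5 (0.27, −0.38), −0.66 for Cd6 (0.13, −0.53) and −0.78 for Exoc2 (−0.08, −0.86). Unnamed probes changed by −0.92 (ILMN_2649828; −0.53, −1.45), −1.15 (ILMN_2601071; −0.36, −1.51) and −1.45 (ILMN_1213055; −0.45, −1.89). Of the 56 splits of the 8 pairs into 3 and 5, 2 called as many as the real 15, the real one included, a share under 5%. The highest other count was also 15, from the 3 hr Th0, 3 hr iTreg and day 1 iTreg pairs against the rest. The pairs come from different cultures, and the real 3 include the day 0 pair, so the splits do not exclude chance.

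For the genotype difference over all conditions, 1 of 100 drawn exchanges of genotype within pairs, the real one, called as many as its 500, and the highest other count was 2. Exchanging the day 0 pair alone was not among those drawn, and it called 744 probes. The 500 therefore stand out only against the splits that were drawn. At day 1 the real split called 576 and the highest other 2, and 1 of 16 splits called as many, which are too few splits for a share under 5%. Before day 1 the real split called 0 by limma (1644 at an unadjusted p under 0.05) and the highest other, with day 0 exchanged, 192, so that 4 of 4 splits called as many. These are too few splits, and the 192 point to a structure of the samples, taken up under the day 0 pair. For the dependence on TGF all 10 splits called 0 (382 at an unadjusted p under 0.05 in the real one), and 10 are too few as well.

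A few probes ran opposite at day 0 to the 7 cultured pairs: of 16 probes that differed by at least 0.5 one way in all 7, 7 differed by at least 0.3 at day 0, and 100% of these were opposite, against 0 in each of the other pairs held out in turn. Red cell RNA in 1 sample is argued against for these probes, since 100% (6 of 6) stayed opposite without red cell genes. The 6 are not independent: they include both Dusp6 probes and ILMN_3159435, which ran with Hba-a1 at day 0 and 3 hr. The slope of the day 0 difference on the mean of the others was −0.67 (95% interval −1.1 to −0.2). An effect of array position alone would give a slope above 0. The slope was taken on the same 16 probes after their direction was seen. It therefore restates that direction and is no separate test of position. The interval comes from resampling the 16 probes and measures no spread between samples. RNA of other cell types was not weighed. Exchanged labels of the arrays labelled WT and Erk2-deficient at day 0 may account for the opposite probes, as Gdpd3 was at 10.12 and 6.63 on these arrays and at 6.74 and 9.48 in 3 hr Th0 culture. A genotype effect that reverses in unstimulated cells cannot be told apart from this, since there was 1 day 0 array per genotype, and across all probes the day 0 differences were nearly unrelated to those of the other pairs (r = −0.12 to −0.016) rather than opposite by as much as these were alike (0.17 to 0.53). With the day 0 labels exchanged 192 probes were called before day 1, against 0 as labelled, which both explanations predict. At day 0, 3 unnamed probes kept their labelled direction (ILMN_2601071 at −0.92, ILMN_2649828 at −0.735 and ILMN_1213055 at −0.73). They were taken as lower in all 8 pairs, day 0 included, so they cannot count against an exchange. Gata3 (0.24), named beforehand, kept its direction too, but it is 1 gene, so the exchange stays open.

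The Erk2-deficient day 1 iTreg array lay towards day 0 on the first principal component. Mixed-in day 0 RNA is argued against, since early response and stress genes gave a median share of 0.022% (interval −2.97 to 0.789) against 8.76% (5.01 to 16.8) for naive and quiescence genes, while all 233 genes high at day 0 gave 12.1% (10.9 to 13.7), the way mixing predicts. These intervals come from resampling genes and measure no spread between samples. By gene the shares ran from −3.06% to 2.33% for early response and stress genes. For naive and quiescence genes they ran from 3.4% to 17.3%. Junb, Klf2 and Tsc22d3 among these genes were also called between genotypes at day 1, which the shares do not allow for. The array was not unusually dim. Its median intensity of 64.4 and its 12358 probes above background lay within the ranges over all arrays (62.6 to 71.1 and 12172 to 12636). A noisy array cannot be told apart, since the correlation of its difference from the WT iTreg array with the day 0 minus day 1 difference restates its position. Across probes this correlation was 0.53 in the median intensity bin, from 0.21 in the dimmest to 0.59 in the brightest. Weaker activation of Erk2-deficient cells in iTreg culture cannot be told apart either, since the medians of the naive and quiescence list (0.509, against 0.0912 to 0.218 in the other day 1 pairs) and of the cell cycle list (−0.158, against 0.00158 to 0.0371) follow from the same position. With 1 array, noise and weaker activation both stay open.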

How the results depend on the processing

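The fits with offset 16, with the day 0 labels exchanged, and without the day 0 or day 1 iTreg pair where a comparison does not use them were chosen after the results were seen. Over all alternatives, named genes kept direction and side of the threshold in 7147 cases, lost their call in 757, gained 1 in 29 and reversed in 0. Gene lists kept theirs in 1748, lost it in 98, gained it in 22 and reversed in 1. Counts stayed within 1.5 times in 167 cases and moved further in 75. Probes near background limit what can be seen, since 12172 to 12636 of 25697 were above it.

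With offset 16 the counts were 275 (genotype, all conditions), 364 (day 1), 5 (by stage), 16 (3 hr against 1 hr of TGF) and 19 (1 hr of TGF against Th0), and 2-fold probes per pair were 11 (day 0), 51 (3 hr Th0), 206 (day 1 iTreg), 26 (1 hr TGF) and 40 (3 hr TGF). Array weights gave 808 (all conditions), 974 (day 1), 277 (before day 1), 82 (by stage), 117 (3 hr against 1 hr of TGF), 112 (Th1 against Th0), 70 (1 hr of TGF) and 433 (3 hr of TGF). For all conditions, limma called 0 with chip as the block (363 at an unadjusted p under 0.05), 0 on chip 1 alone (1411), and 140 with condition as a random block. A trended robust prior gave 1 before day 1. Exchanged day 0 labels gave 192 before day 1 and 71 by stage, and the red cell list by stage reversed to 0.668 (adjusted p = 0.017).

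Leaving out 1 pair or array gave 148 to 968 (all conditions), 232 to 921 (day 1), 0 to 500 (before day 1), 4 to 179 (by stage), 0 to 1 (3 hr iTreg against Th0), 503 to 2291 (iTreg against Th1), 7 to 71 (3 hr against 1 hr of TGF), 4 to 53 (Th1 against Th0), 383 to 1720 (iTreg against Th0), 0 to 49 (1 hr of TGF) and 50 to 282 (3 hr of TGF). Where 1 array of a culture was left, it was assumed to vary like the others. The counts of 0 by limma had 1120 and 829 (before day 1), 473 to 778 (3 hr iTreg against Th0) and 493 (1 hr of TGF) at an unadjusted p under 0.05. Fewer arrays give fewer calls in part of these, and otherwise the cause was not tested. The neqc alternatives were not run.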

Other observations

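The tests of both hypotheses in this part were chosen after the results were seen.

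Between day 0 and Th0 culture some stress response, survival and DNA methylation genes changed too, with none of these 3 lists called by camera. Whether activation was the cause was not tested. By day 1 in Th0 culture the serine synthesis enzymes Psat1 (log2 change 2.91, SE 0.119, adjusted p = 1.85e-11, higher in 2 of 2 genotypes) and Phgdh (1.94) and the one-carbon enzyme Shmt2 (1.99) had risen against day 0, while the stress factor Ddit3 fell (−2.56). Of 13 integrated stress response genes 6 rose and 3 fell, with 7 and 4 when adjusted over the list alone (camera adjusted p = 0.553). The survival genes Bcl2l1 (2.78) and Bcl2a1d (1.82) rose and Mcl1 fell (−1.39), in a list of 12 apoptosis regulators of which 3 rose and 6 fell, with 3 and 6 when adjusted over the list alone (camera adjusted p = 0.593). Dnmt1 (1.88), which maintains DNA methylation, its partner Uhrf1 (3.31) and Dnmt3b (1.13) rose, and Gadd45a fell (−3.53), with 3 of 7 DNA methylation genes up and 3 down by either count, the second adjusted over the list alone (camera adjusted p = 0.659). At 3 hr Uhrf1 had fallen instead (−0.89 on the brighter of its probes), and Gadd45b (1.24) had risen.

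In single pairs, with no test, differences beside those in the report included higher Chil3 (0.95) and Erdr1 (0.91) and lower Trnp1 (−3.16) at day 0, higher Dpcd (0.98) in 3 hr iTreg culture, higher Tsc22d3 (2.05) and lower Polr1a (−1.56) in day 1 iTreg culture, and higher Emp1 (1.37) with 3 hr of TGF. The day 1 iTreg pair had 118 probes that differed at least 2-fold, 84 higher and 34 lower, against 19 in day 1 Th0.

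A first hypothesis was that genes which rose after 1 hr of TGF at day 1 may also rise in iTreg culture at 3 hr. For these 22 genes the median change between 3 hr iTreg and Th0 culture was −0.011, 6 were higher in both genotypes, and camera gave p = 0.889 (p = 0.927 with an estimated correlation), so the data did not bear it out. A second was that genes higher in iTreg than in Th1 culture may be higher in Erk2-deficient cells without iTreg culture. For the 89 genes at least 2-fold higher in iTreg culture, the median genotype difference was 0.046 in day 1 Th0, 0.14 with 1 hr and 0.18 with 3 hr of TGF. Of these genes 42 were higher and 20 lower in all 3 pairs, and camera gave p = 3.29e-06, but p = 0.144 with an estimated correlation, so the call rests on the preset correlation.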
